A study of Mus musculus with 4 samples.

How the data were processed

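DNase-seq data of 3T3-L1 cells, with no treatment named, were used, from 4 libraries of 2 biosamples. The labels number the biological and technical replicates, and the grouping follows the biological replicate number. Per the labels, the authors made 1 alignment for each biosample from both of its libraries and called peaks and hotspots on it in the assembly mm10, so the lists are of pooled libraries and the technical libraries could not be compared. The aligner, the peak caller and their versions were not given in the sources used here. The labels do not say whether the biosamples were separate cultures, so differences between them may be technical.

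Each deposited peak list holds windows of at most 150 bp with a score, a whole number up to 150 whose definition was not given in the sources used here. The score is the authors' own value per peak and was used only to rank peaks within a list, as a percentile or decile. Its median was 65 in biosample 1 (quartiles 46 and 97) and 33 in biosample 2 (22 and 50), and these values cannot be compared between lists. Each deposited hotspot list gives a −log10 q value for each region, from 1.30 up to a cap of 100, which 49.4% of the hotspots of biosample 1 and 42.8% of those of biosample 2 reached, so hotspots were not ranked. Depth per library was unknown, because the lists hold no read counts. A shallower biosample would yield fewer and mostly stronger sites, which limits every comparison of list length.

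Choices were made before the data were examined, except where a result is said to have been added later. The reference GRCm38.p6 has the chromosome sequences of mm10, and every interval on chromosomes 1 to 19, X and Y was checked to lie within its lengths. Genes were taken from GENCODE M21. Annotation records that gave the same symbol more than once on a chromosome, 24 in number, were merged, which left 21,829 protein-coding genes with 54,355 start sites. Features were assigned on chromosomes 1 to 19, X and Y in the order promoter (within 1000 bp of a protein-coding start site), exon, intron and intergenic. Peaks or hotspots were shared when they met by at least 1 bp in bedtools 2.31.1. Chance overlap came from 100 rotations of the peaks along each chromosome (seed 1). Shares have 95% Wilson intervals, and the interval of Spearman's rho came from 200 bootstraps over peaks. All intervals cover counting error only.

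A gene was called open when a peak lay within 1000 bp of any of its start sites in both lists. The 16 gene lists with 265 genes in all were taken from textbook knowledge: adipogenic transcription factors, mature adipocyte genes, preadipocyte and anti-adipogenic genes, fibroblast and matrix genes, Hippo and AP-1 genes, cell cycle genes, housekeeping genes, Hox genes, and genes of bone and cartilage, skeletal muscle, hepatocytes, neurons, blood cells, epithelia, endothelium and pluripotent cells. Each was set against all other protein-coding genes with a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05, and 5 pairs of lists were compared in the same way. Genes are not replicates, and such a p-value describes these lists, not the spread between cultures. A gene's promoter was CpG-rich when its observed over expected CpG ratio was at least 0.6 in the 1000 bp centred on the most upstream start site. That start site can differ from the one with the peak. The comparison within 5 classes of the CpG ratio used an exact conditional test over the classes with Mantel-Haenszel odds ratios. Where every gene of a list was open, that ratio is not finite. The odds of the list over those its classes give were then used, with a small constant added to both counts.

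Motif matches on either strand were counted in windows of 200 bp centred on shared peaks over 1000 bp from any protein-coding start site. The 22 consensus motifs included AP-1 (TGASTCA), TEAD (CATTCCW), C/EBP (RTTGCNYAAY), CTCF (CCASYAGRKGG), RUNX (TGTGGTTW) and EBF (TCCCNNGGGA). Control windows lay outside all peaks and hotspots and were matched for GC content from 150,000 draws per chromosome, which left 72,059 of 72,124 windows with a control. They were not matched for CpG or repeat content, which limits the ratios of motifs that hold a CpG (CRE, ETS, SP/KLF and NRF1). Fisher's exact test was two-sided with Benjamini-Hochberg adjustment over the motifs. A consensus match is not evidence of binding, and a strict consensus misses degenerate sites.

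The named genes follow a rule fixed in advance: of each list the 4 members with the highest mean score percentile and up to 4 without a peak in either list, with any member of the adipogenic, mature adipocyte and preadipocyte lists; the 10 strongest shared distal and 10 strongest shared promoter peaks; the 10 genes nearest to the most shared distal peaks; the 5 strongest promoter peaks of each list alone; and the 5 widest hotspots of each list. Some genes that the rule gives are not reported here. Members of the fibroblast and Hippo lists that were open in biosample 1 alone, the genes in blocks, the Pparg start sites and Gm21860 were named after their values were seen.

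The alternatives were an overlap of 50% of the shorter peak, the stronger 50% of each list, the longer list shortened to the length of the other, autosomes only, promoter windows of 500 and 2000 bp, the most upstream start site, hotspots in place of peaks, the list of either biosample alone, and sites over 5000 bp from any start site, each changing 1 choice. Flanking control windows, in which 54,900 of the 72,124 windows could be used, also changed the GC content, which was not matched (43.8% in controls and 47.1% in peaks). Alternatives added after the data had been seen were the stronger 50% of a list against the whole other list, the promoter comparison within score deciles, the gene list test within CpG classes, and the removal of the blocks of dense strong peaks. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The code was tested on simulated data: an overlap planted at 70% in 5000 peaks was recovered as 70%, and of lists of 20 genes among 20,000, 99% of those made 95% accessible, 100% of those made 10% accessible and 2% of those made 60% accessible, the background, were called. Peaks on unplaced scaffolds and the mitochondrial genome were left out of the feature, gene and motif comparisons.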

Results

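3T3-L1 is a mouse line of embryonic fibroblasts that is committed to the fat lineage and turns into adipocytes after confluence, faster under hormonal induction. Its open chromatin was mapped by DNase-seq, in which DNase I cuts accessible DNA and the cut ends are sequenced. No treatment is named in the labels. The 4 libraries came from 2 biosamples with 2 technical libraries each, and for each biosample the authors deposited 1 list of peaks, windows of at most 150 bp, and 1 list of hotspots, which are regions of enriched cleavage of varying width. Biosample 1 had 298,793 peaks and 247,031 hotspots and biosample 2 had 97,430 peaks and 88,636 hotspots, so that the lists of biosample 1 were 3.07 and 2.79 times as long. Hotspots covered 108 Mb, or 3.96% of the chromosomes, in biosample 1 and 30.5 Mb, or 1.12%, in biosample 2, with median widths of 272 and 273 bp. Read depth was unknown. With 1 list per biosample no spread between replicates could be had, so the 95% intervals cover counting error over peaks or genes, which are not replicates.

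The comparison that the design implies is between the biosamples: how far the same sites were accessible in both. Of 21,829 protein-coding genes, 11,318 (51.8%) had a promoter peak in both lists, 2,349 in biosample 1 alone and 22 in biosample 2 alone, while 8,140 (37.3%) had none. Among the strongest promoter peaks present in both lists were those of Nqo1, a quinone reductase induced by oxidative stress (chromosome 8, 107,403,116–107,403,265, mm10, 15 bp from the start site), and Rfx1, which encodes an X-box binding factor (chromosome 8, 84,066,496–84,066,645), each with a score of 150 in biosample 1 and 116 in biosample 2. The other 8 of these 10 lay at Cwc22, Mdm2, Slc35e3, Rnf5, Evi5l, Zbtb3, Wbp1l and Prcc. The score is the authors' own value per peak and was read only within its list, where 150 was the highest value in both.

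Most biosample 2 peaks met a biosample 1 peak. Of the 97,430 peaks of biosample 2, 91,112 (93.5%, 95% Wilson interval 93.4 to 93.7) met a peak of biosample 1 by at least 1 bp, against a mean of 3.39% and a highest value of 3.63% over 100 rotations of the peaks along their chromosomes. In the other direction 90,934 of 298,793 peaks (30.4%, 30.3 to 30.6) met a biosample 2 peak, with 1.11% after rotation. Hotspots gave 98.5% (98.4 to 98.6) of biosample 2 and 30.7% (30.5 to 30.9) of biosample 1. Across the 90,934 shared peaks, which are not independent replicates, the scores of both lists ranked alike, with a Spearman rho of 0.907 (bootstrap interval 0.905 to 0.908). When the longer list was shortened to the strongest peaks, as many as the other list had, 76.5% of the biosample 1 peaks were shared, and the stronger 50% of the biosample 1 list met the whole biosample 2 list in 57.3%.

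Sharing followed the score. In biosample 1 the share found in biosample 2 went from 1.35% (1.23 to 1.49) in the lowest score decile to 94.5% (94.2 to 94.8) in the highest. In biosample 2 it went from 76.8% (76.0 to 77.6) to 98.5% (98.2 to 98.7). The 6,318 peaks of biosample 2 that met no biosample 1 peak, of which 79.3% lay in a biosample 1 hotspot or within 150 bp of one of its peaks, were low in their list, at a median score percentile of 18.6 against 52.0 for its shared peaks.

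**Figure D1:**
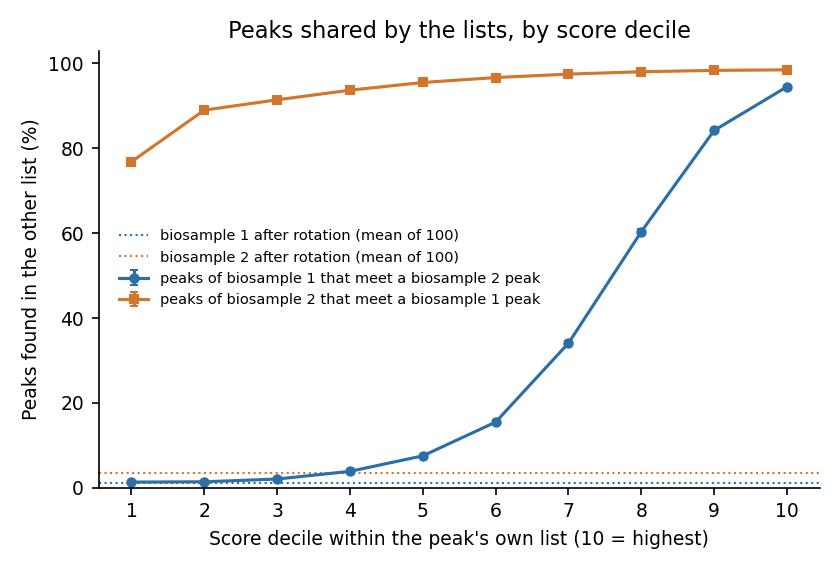
Share of peaks (%) that met a peak of the other list, by score decile within the peak's own list (10 is the highest), with 95% Wilson intervals mostly smaller than the symbols and dotted lines for the mean of 100 rotations. The biosample 1 curve climbs from 1.35% to 94.5% and the biosample 2 curve stays between 76.8% and 98.5%.

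Promoters held more of the accessible sites than chance placement gave. Within 1000 bp of a protein-coding start site lay 13.3% (13.2 to 13.5) of the biosample 1 peaks, 4.97 times the share of rotated peaks, and 21.7% (21.5 to 22.0) of the biosample 2 peaks, 8.04 times that share. Introns held 38.2% and 33.8%, exons 3.61% and 2.88%, and intergenic sequence 44.8% and 41.6%. Genes with CpG-rich promoters had a peak in both lists in 8,159 of 10,173 cases (80.2%), and those with CpG-poor promoters in 3,159 of 11,656 (27.1%). With a window of 500 bp the promoter share of biosample 1 was 8.77%.

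Promoter sites were 20.5% of the shared peaks, 10.2% of the peaks of biosample 1 alone and 36.0% (34.9 to 37.2) of the peaks of biosample 2 alone. Shared peaks against those of biosample 1 alone had an odds ratio of 2.28 (2.23 to 2.33) by Fisher's exact test on peaks. With promoter windows of 500 and 2000 bp it was 3.48 (3.39 to 3.57) and 1.68 (1.64 to 1.71). The direction of the odds ratio turned once peaks of like score were compared: within deciles of the biosample 1 score the Mantel-Haenszel odds ratio was 0.561 (0.543 to 0.580), and 0.706 (0.682 to 0.730) with a biosample 2 hotspot also counting as shared, both computed after the first value was seen. Some promoters had peaks in each list that did not meet. The strongest unmatched promoter peaks of biosample 1 lay at Mdm2, Slc35e3, Ska2, Fbxo24 and Lyz2, and those of biosample 2 at Mdm2, with 2 peaks, Slc35e3, Fbxo24 and Lyz2.

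Connective tissue and growth genes had open promoters in both biosamples. Of 23 fibroblast and matrix genes 21 had a promoter peak in both lists (91.3%, 73.2 to 97.6), an odds ratio of 9.77 (2.29 to 41.7) against all other protein-coding genes by Fisher's exact test (adjusted p = 4.3e-04 over 16 lists). They included Vim, the intermediate filament protein of mesenchymal cells, with scores of 146 and 90 in biosamples 1 and 2, the fibrillar collagen genes Col1a2 (148 and 87) and Col5a2 (144 and 79), and the calcium-binding S100a4 (141 and 88). Fap and Lum had a peak in biosample 1 alone. Hippo and AP-1 genes, the growth-control and immediate early factors, were open in 18 of 20 (odds ratio 8.37, 1.94 to 36.1, exact test, adjusted p = 0.0019), with Fosl2 (145 and 102), Jun (144 and 94), Jund (143 and 84) and the YAP target Amotl2 (140 and 78) leading. Fosl1 and Tead1 had a peak in biosample 1 alone. All 17 cell cycle genes were open in both (exact test, adjusted p = 2.9e-04), led by the replication genes Pcna (149 and 106), Mcm3 (149 and 104) and Mcm5 (145 and 89) and by E2f1 (147 and 87), as were all 15 housekeeping genes (exact test, adjusted p = 4.3e-04), among them Eef1a1 and Rpl13a (145 and 95 each), Gapdh (146 and 90) and B2m (145 and 89).

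Regulators of fat cell formation were mostly open in these cells, for which no induction is named, and genes of the mature fat cell were split. Of 19 adipogenic transcription factors 16 had a promoter peak in both lists (84.2%, 62.4 to 94.5, odds ratio 4.96, 1.44 to 17.0, exact test, adjusted p = 0.0098) and all 19 had one in biosample 1. The call was lost in exact tests with the most upstream start site of each gene only (1.47, adjusted p = 0.542), with the stronger 50% of each list (2.00, adjusted p = 0.193) and within 5 classes of promoter CpG ratio (2.62, adjusted p = 0.160). Ebf1 (142 and 89), Nfia (143 and 85), Egr2 (145 and 79) and the glucocorticoid receptor gene Nr3c1 (140 and 76) had the strongest peaks. The early inducers Cebpb (125 and 37) and Cebpd (146 and 62) were open in both lists, as were Pparg (105 and 29) and Srebf1 (136 and 49). Cebpa (99 in biosample 1), Klf15 and Nr1h3 had a peak in biosample 1 alone. They were absent only from the shorter list, so no order by stage of differentiation can be read from this. Of 20 mature adipocyte genes 10 were open in both lists and 14 in biosample 1 (odds ratio 0.929, 0.386 to 2.23, exact test, adjusted p = 1). Within the CpG classes their ratio was 1.504 (0.525 to 4.305), and its interval overlaps that of the adipogenic factors (2.62, 0.7597 to 9.04). Promoters were CpG-rich in 5 of the 20 mature adipocyte genes and in 12 of the 19 factors. Both lists were not compared directly within CpG classes, so their contrast cannot be told apart from promoter CpG content. The lipid-synthesis genes Scd1 (144 and 89) and Fasn (138 and 66), the hormone-sensitive lipase gene Lipe (132 and 74) and Lpl (136 and 59) were open. Fabp4, Cd36, Cidec and Lep had a promoter peak in biosample 1 alone. The adipokine genes Adipoq, Cfd and Retn, with Cidea, Pck1 and the thermogenic Ucp1, had none in either list.

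Preadipocyte and anti-adipogenic genes were open in 11 of 18 (odds ratio 1.46, 0.566 to 3.77, exact test, adjusted p = 0.518). The Notch target Hes1 (149 and 97), the stress factor gene Ddit3 (142 and 92), Sox9 (140 and 76) and the growth factor receptor gene Pdgfrb (136 and 75) led this list. Dlk1, the preadipocyte inhibitor of differentiation, and Nr2f2 had a promoter peak in biosample 1 alone, and Cd34, Dpp4, Wnt10a, Wnt10b and Wnt6 had none in either list. In direct exact tests between lists, the fibroblast and matrix genes were open more often than the mature adipocyte genes (odds ratio 10.5, 1.93 to 57.2, adjusted p = 0.0086 over 5 pairs), and the adipogenic factors did not pass against the mature adipocyte genes (5.33, 1.17 to 24.2, adjusted p = 0.0509), nor did the preadipocyte genes (1.57, adjusted p = 0.532).

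Genes of other lineages mostly lacked a peak within 1000 bp of a start site in both lists. Blood cell genes were open in 1 of 14 (odds ratio 0.0714, exact test, adjusted p = 0.0022), the exception being the macrophage receptor gene Csf1r (125 and 44), while Cd3e, Cd4 and Cd79a had no peak. Hepatocyte genes were open in 1 of 12 (0.0843, exact test, adjusted p = 0.0058), with Apob (111 and 46) open and Alb, Afp, Ahsg and Apoa1 without a peak. Pluripotency genes were open in 1 of 10 (0.103, exact test, adjusted p = 0.0165), which was Tdgf1 (71 and 16), and Nanog, Sox2, Esrrb and Dppa5a had no peak. Bone and cartilage, skeletal muscle, neuron and epithelial genes were each open in 3 of 12 and endothelial genes in 2 of 10, which did not pass the exact test (adjusted p = 0.0945 for each of the former and 0.0916 for the latter). The open members were Runx2 (134 and 43), Spp1 (130 and 44) and Dmp1 (120 and 38) of bone, Pax3 (120 and 42), Tnnt3 (95 and 17) and Myh1 (86 and 19) of muscle, Rbfox3 (96 and 27), Snap25 (97 and 26) and Gad1 (97 and 22) of neurons, Elf3 (120 and 62), Krt8 (125 and 45) and Grhl2 (91 and 24) of epithelia, and Pecam1 (112 and 40) and Cdh5 (84 and 33) of endothelium. Members without a peak in either list included Acan, Alpl, Bglap, Col10a1, Acta1, Ckm, Des, Myf5, Elavl4, Neurod1, Neurog2, Cdh1, Epcam, Krt14, Krt18, Emcn, Flt1, Kdr and Sox17. Against both bone and muscle genes, the fibroblast and matrix genes had an odds ratio of 31.5 (4.47 to 222, exact test, adjusted p = 3.4e-04).

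Hox genes, which keep the positional identity of mesenchymal cells, were open in both lists in 10 of 39 (odds ratio 0.320, 0.156 to 0.656, exact test, adjusted p = 0.0030). Hoxa5 (140 and 83), Hoxa3 (137 and 84) and Hoxc13 (134 and 66) were among those with the strongest promoter peaks, and Hoxa11, Hoxa13, Hoxb1 and Hoxb3 had none. By the list of biosample 1, taken without that of biosample 2, 22 of the 39 were open and the call was lost (0.772, exact test, adjusted p = 0.473).

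**Figure D2:**
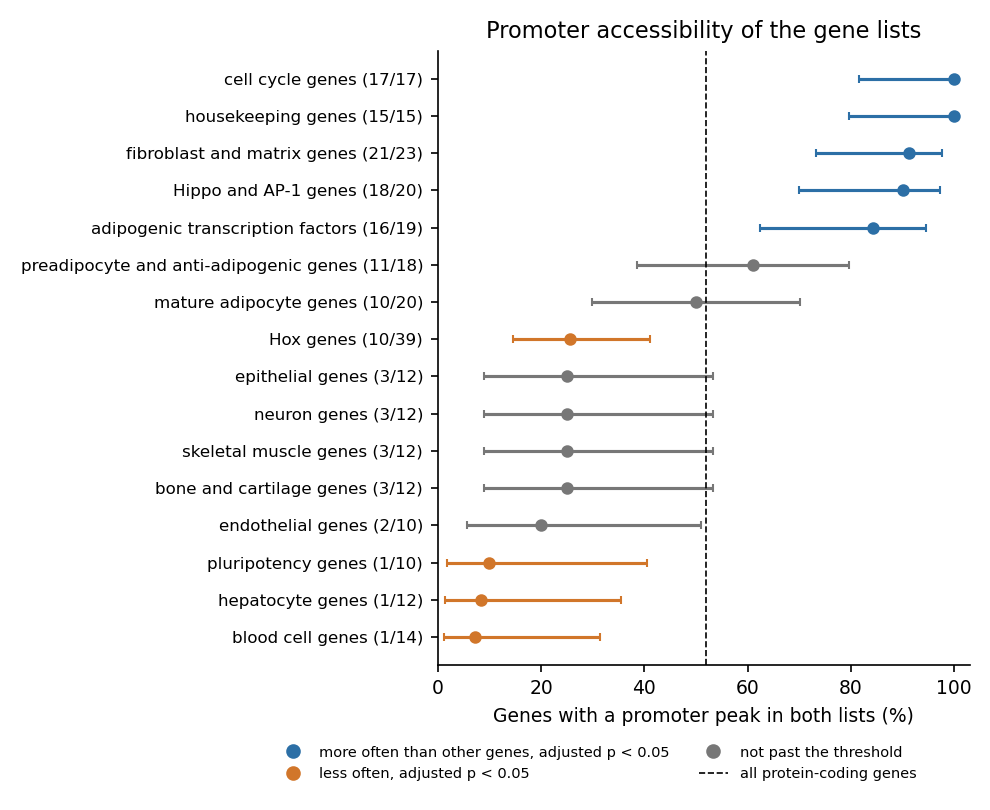
Percentage of the genes of each of 16 lists with a promoter peak in both lists, with 95% Wilson intervals and the number of open and tested genes, and a dashed line at the 51.8% of all protein-coding genes. Lists that passed at an adjusted p of 0.05 are coloured, 5 above the line and 4 below it.

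In all, 5 lists were open more often than other genes and 4 less often. Compared within 5 classes of promoter CpG ratio, in an exact test added after these results, the calls of the adipogenic factors and cell cycle genes were lost. For the cell cycle genes, with 17 of 17 open, the odds were 10.8 times those that their classes give (exact test, adjusted p = 0.0664). Hepatocyte genes (odds ratio 0.246, exact test, adjusted p = 0.248) and blood cell genes (0.218, adjusted p = 0.0978) lost their calls too. In that exact test the fibroblast and matrix genes kept theirs (14.1, adjusted p = 1.6e-06), as did the Hox genes (0.199, adjusted p = 5.9e-07), and the neuron genes gained one (0.341, adjusted p = 0.0421). The call of the pluripotency genes ended in the exact test when the list of biosample 1 was used without the other (0.398, adjusted p = 0.234), and with a promoter window of 500 bp 9 lists were open less often. Other-lineage values depended on the setting. In a window of 2000 bp bone and cartilage genes were open in 6 of 12 (odds ratio 0.801, exact test, adjusted p = 0.827) and muscle genes in 5 of 12 (0.572, adjusted p = 0.481). The neuron list had 0 of 12 open in the stronger 50% of each list (exact test, adjusted p = 0.0027), 1 of 12 by the most upstream start site (adjusted p = 0.0118), 5 of 12 by hotspots (0.656, adjusted p = 0.606) and 7 of 12 in a window of 2000 bp (odds ratio 1.12, adjusted p = 1). Muscle genes passed with the stronger 50% of each list (0.106, exact test, adjusted p = 0.0129) and endothelial genes with the most upstream start site (0.119, adjusted p = 0.0354).

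The gene of the nuclear receptor PPARγ, the master regulator of adipogenesis, showed the difference between the lists at a single locus. Pparg (chromosome 6, 115,360,951–115,490,399, mm10, plus strand) held 37 biosample 1 peaks, 29 of them intronic, and 14 biosample 2 peaks, and 13 of the 37 were shared. Of its annotated start sites only the most downstream, at 115,422,066, from which the adipocyte-enriched isoform is transcribed, had a peak within 1000 bp in both lists. The strongest of the 3 biosample 1 peaks there spanned 115,421,096–115,421,245 with a score of 105, at percentile 79.97 of its list, and the biosample 2 peak spanned 115,421,116–115,421,265 with a score of 29, at percentile 42.1. Both of these peaks lay over 500 bp upstream of the start site. With a promoter window of 500 bp, Pparg thus had no biosample 2 peak at any start site. At the most upstream start site, 115,360,951, biosample 1 had 3 peaks with a top score of 66 and biosample 2 had 0.

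**Figure D3:**
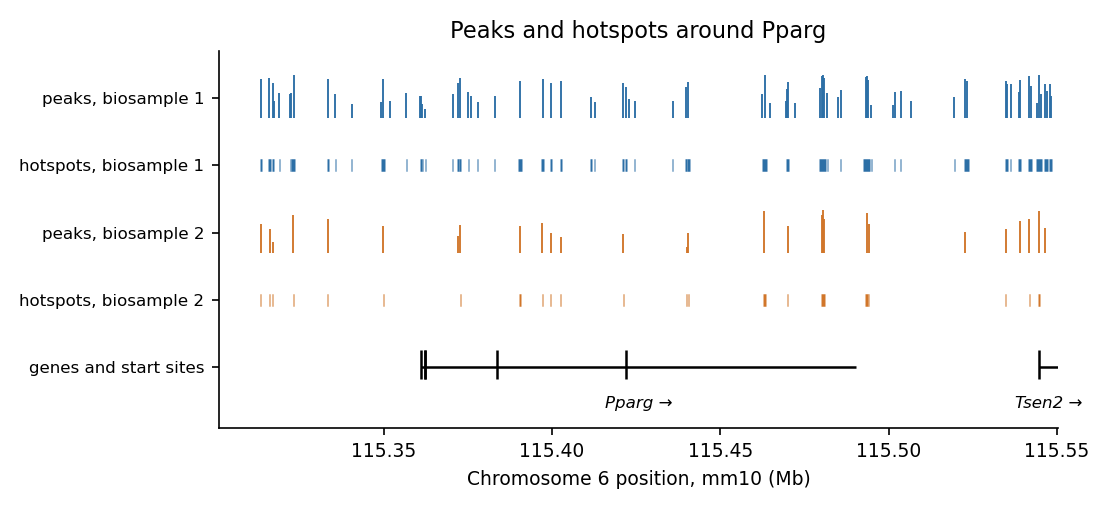
Peaks (bar height is the score percentile within the list) and hotspots of both biosamples along chromosome 6 (mm10, Mb) around Pparg, with genes and annotated start sites as vertical ticks. Biosample 1 has 37 peaks and biosample 2 has 14 across the gene.

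AP-1 and CTCF motifs stood out at distal sites. AP-1, the dimer of Fos and Jun proteins, had a match in 29.7% (29.4 to 30.0) of 72,059 shared distal windows of 200 bp and in 2.82% of as many control windows of equal GC content, an odds ratio of 14.6 (13.9 to 15.3). CTCF, the insulator factor, had a match in 9.53% (9.31 to 9.74) against 0.251% (odds ratio 41.8, 36.1 to 48.5), and the Hippo effector TEAD in 14.5% against 7.60% (2.07, 2.00 to 2.14). RUNX, the factor family of mesenchyme and bone, had 6.26% against 1.93% (3.39, 3.19 to 3.60). Among motifs of factors with adipogenic roles, C/EBP was found in 1.43% against 0.450% (3.22, 2.84 to 3.65), EBF in 1.13% against 0.473% (2.40, 2.11 to 2.72) and full-length NF1 sites in 0.0708% against 0.00833% (8.51, 3.65 to 19.8). The glucocorticoid receptor motif was found in 0.148% and 0.142% (1.05, Fisher's exact test, adjusted p = 0.819). The DR1 element, to which PPARγ binds with its partner RXR, was found in 0.0278% and 0.0472% (0.588, 0.338 to 1.02, Fisher's exact test, adjusted p = 0.0904). The NF1 ratio was 3.22 (1.53 to 6.81) beyond 5000 bp from any start site and 18.0 (2.40 to 135) in the stronger 50% of the windows. Against flanking windows not matched for GC content it was 38.0 (5.22 to 277). Control shares were only 0.00278% for the stronger 50% and 0.00182% for flanking windows, so very few matches set these ratios, and the intervals overlap. The DR1 ratio was 1.21 for all distal biosample 1 peaks (exact test, adjusted p = 0.214) and 0.350 beyond 5000 bp (adjusted p = 9.0e-04). Beyond 5000 bp the share of peaks was nearly unchanged, at 0.0282%, and the control share was higher, at 0.0806%. Few matches set this ratio as well, and its fall came from the controls, so it does not show a loss of DR1 in peaks.

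Of 22 motifs 14 were more frequent in shared distal windows than in controls and 2 less frequent. The further ones above controls were CRE (odds ratio 2.60), ETS (2.01), STAT (1.77), PU.1 (1.70), SP/KLF (1.51), NRF1 (3.67, Fisher's exact test, adjusted p = 0.0055) and SRF (1.13, adjusted p = 0.0249). GATA (0.914, exact test, adjusted p = 8.3e-07) and OCT (0.863, adjusted p = 0.0052) lay below. In the same exact test NFY (adjusted p = 0.115), MEF2 (0.0638), the glucocorticoid receptor (0.819), HNF4 (0.0904) and HNF1 (1) did not pass. For all distal biosample 1 peaks the glucocorticoid receptor (1.25, exact test, adjusted p = 0.0019) and HNF4 (1.22, adjusted p = 2.0e-04) did pass and MEF2 lay below controls (0.960, adjusted p = 0.0402). For distal biosample 2 peaks MEF2 lay above them (1.11, exact test, adjusted p = 0.0039). NFY passed in the stronger 50% of the windows (1.15, exact test, adjusted p = 0.0027) and against flanking windows (1.3, adjusted p = 6.4e-11). The NRF1 call depended on the choice of windows, with an odds ratio of 0.808 (exact test, adjusted p = 0.404) for all distal biosample 1 peaks and of 1.00 (adjusted p = 1) beyond 5000 bp from any start site, as did SRF, at 0.981 (adjusted p = 0.488) for all distal biosample 1 peaks. The OCT call ended in the stronger 50% of the windows (0.885, exact test, adjusted p = 0.122). For all distal biosample 1 peaks AP-1 had an odds ratio of 9.46 and CTCF of 19.8, and flanking controls, not matched for GC content, gave CTCF 78.9, EBF 3.70 and MEF2 0.575.

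**Figure D4:**
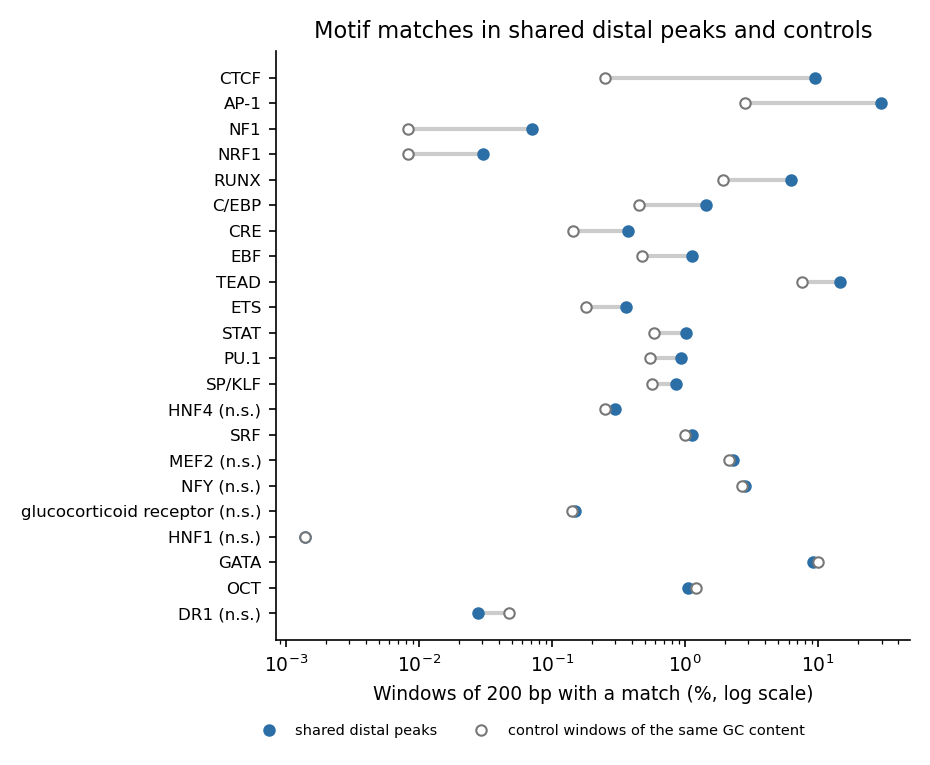
Percentage of 200 bp windows with a motif match (log scale) in shared distal peaks (filled) and in control windows of equal GC content (open), for 22 motifs ordered by odds ratio, with n.s. marking an adjusted p above 0.05. AP-1 stands at 29.7% against 2.82% and CTCF at 9.53% against 0.251%.

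AP-1 matches were most frequent among the strongest sites and CTCF matches just below them. Along the score deciles of biosample 1 the share of distal windows with an AP-1 match went from 13.9% to 39.0%, while CTCF went from 1.61% to 11% in decile 9 and 3.66% in decile 10. Among peaks of like score, CTCF matches were more frequent in shared peaks than in peaks of biosample 1 alone, with a Mantel-Haenszel odds ratio over deciles of 4.07 (3.83 to 4.33), and the ratios of MEF2 (1.37, 1.26 to 1.5), OCT (1.2, 1.06 to 1.36), AP-1 (1.17, 1.13 to 1.2), GATA (1.11, 1.06 to 1.16) and RUNX (1.11, 1.05 to 1.17) were smaller. Without regard to score GATA matched 9.18% of shared peaks and 10.1% of peaks of biosample 1 alone, so that its direction turned within deciles. OCT had nearly equal shares, 1.05% and 1.07%. In decile 10 RUNX matched 7.62% of shared windows and 3.52% of those of biosample 1 alone, against 5.98% and 6.10% in decile 9. Of the 1,222 decile 10 windows of biosample 1 alone, 461 lay outside the blocks of dense strong peaks described below. The ratios of MEF2, OCT, GATA and RUNX were not recomputed without these blocks.

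Nrg1 and Zeb2 had the most shared distal sites. As nearest gene, Nrg1, a ligand of ErbB receptors, and Zeb2, a repressor of epithelial genes, each had 79 shared distal peaks, Pde4d 77, Lin7a 72, Efnb2 68, Myc 64, Klf6 and Mdm2 61 each, Cwc22 58 and Ets1 57, where the median protein-coding gene had 1 and the 99th percentile was 28. Each peak was assigned to its nearest start site, with no allowance for gene length or the distance to neighbouring genes, so these counts are not densities. For Myc, the growth-promoting transcription factor gene, the shared peaks came from 249 distal peaks of biosample 1 and 68 of biosample 2. The widest hotspot of biosample 1, of 14,243 bp (chromosome 6, 4,529,638–4,543,880, mm10), overlapped the downstream part of the collagen gene Col1a2, ran past its annotated end at 4,541,544 and met no biosample 2 hotspot. The others lay at Kdm6b and Dnah2 (12,673 bp), Fgf7 and Fam227b (12,243 bp) and Tnrc18 (12,080 bp) and near Ubash3b (11,672 bp), and those of biosample 2 near Lin7a (9,233, 8,836 and 8,705 bp), at Hes1 (7,837 bp) and near Cwc22 (6,899 bp).

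The very strongest distal sites gathered at few places. The top shared distal peak lay between genes 11,093 bp from the start site of Mdm2, the gene of the ubiquitin ligase that degrades p53 (chromosome 10, 117,721,776–117,721,925, mm10), with a score of 150 in both lists. Of the 20 strongest shared peaks that the naming rule gave, 13 were assigned to Mdm2, Cpm, Slc35e3 or Cwc22. These lay in blocks of densely packed strong peaks, defined after the clustering had been seen as bins of 50 kb with at least 25 biosample 1 peaks and a median score percentile of at least 88. There were 5 blocks with 800 kb in all, which held 1,296 peaks of biosample 1 (0.435%) and 467 of biosample 2. The largest, chromosome 10, 117,350,001–117,800,000, spanned Cpsf6, Cpm, Mdm2, Slc35e3 and Nup107 with 881 and 235 peaks, and the block around Cwc22, chromosome 2, 77,850,001–78,050,000, had 273 and 96. The others were chromosome 10, 117,250,001–117,300,000, at Lyz2 and Lyz1 (37 and 28 peaks), 107,200,001–107,250,000, near Lin7a (77 and 80), and 118,600,001–118,650,000 (28 and 28).

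**Figure D5:**
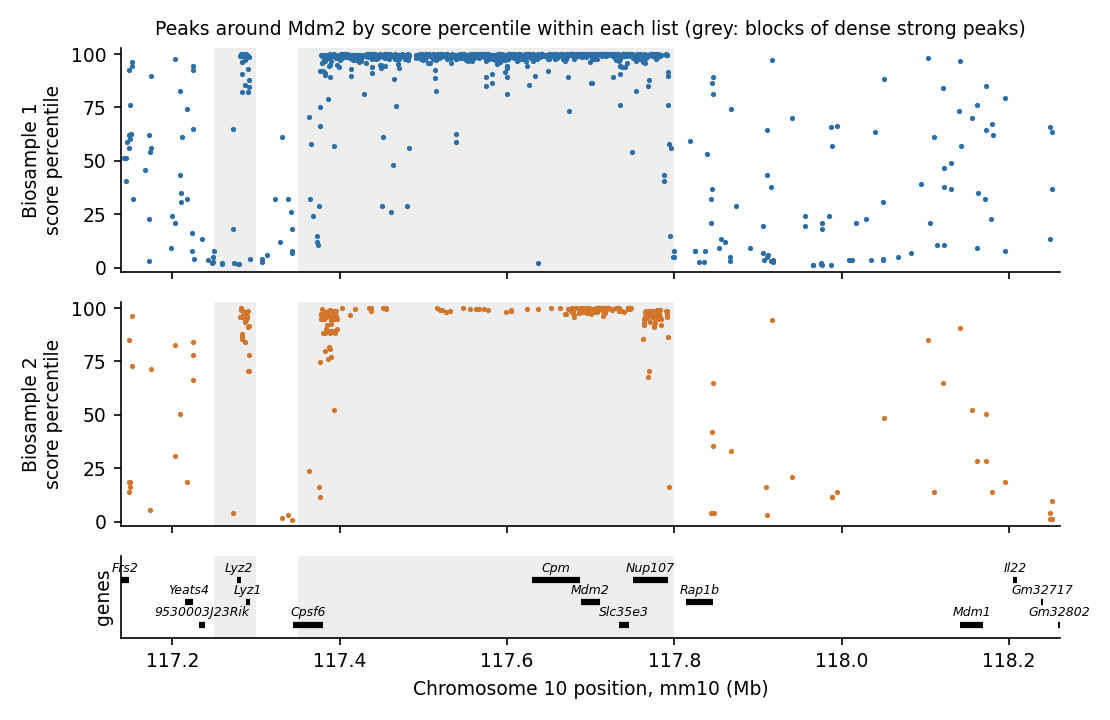
Score percentile within the list of each peak of biosample 1 (top) and biosample 2 (middle) along chromosome 10 (mm10, Mb) around Mdm2, with genes below and blocks of dense strong peaks in grey. Within the block of 450 kb the 10th percentile of the score percentiles is 96.0 in biosample 1 and 90.1 in biosample 2.

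No autosome stood far from the others in the ratio between the lists. The ratio of biosample 1 to biosample 2 peaks had an autosomal median of 3.05, from 2.77 on chromosome 19 to 3.38 on chromosome 14, a highest over lowest ratio of 1.22 (1.15 to 1.29). Chromosome X had a ratio of 3.42, 1.12 times the autosomal median (1.07 to 1.17), and 51.5 and 15.1 peaks per Mb in biosamples 1 and 2 against autosomal medians of 118 and 39.2.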

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

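The rule for the blocks of dense strong peaks, the 7 comparison genes, the values outside the blocks and the AP-1 share within them were chosen after the clustering of strong peaks was seen, and the other tests in this part were set before their values were computed. Sequence outside the chromosome comparisons also held peaks. The mitochondrial genome had 17 peaks in each biosample, with a median score of 150 in both lists. Unplaced scaffolds had 564 peaks in biosample 1 and 153 in biosample 2.

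Chromosome Y held 101 peaks in biosample 1 and 27 in biosample 2. Of these, 29 and 9 lay in its first 5 Mb and 64 and 17 in its last 5 Mb, 0 lay in a promoter, and their median scores were 30 and 23. The 64 biosample 1 peaks of the last 5 Mb were not spread over it but formed a single cluster near Gm21860. Scores in this cluster ran from 13 to 141, and its strongest peak met a biosample 2 peak, so the median hides strong peaks there. Kdm5d, Eif2s3y, Uty and Ddx3y are broadly expressed genes of the Y short arm. None of their promoters had a peak in either list, so 0 of the 4 had one in both. Reads of repeated or X sequence placed on Y may explain the Y peaks that were called. Over 50% of the bases were masked as repeats in 56 and 11 of the Y peaks, so masked sequence does not hold all of them. A Y chromosome that is present with these promoters closed remains open, and no biological explanation was tested.

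Biosample 1 had 3.07 times as many peaks as biosample 2. Calls in repeats are argued against as the main source, since 12.9% of the peaks of biosample 1 alone had over 50% of their bases masked, against 5.97% of its shared peaks. Lower detection in biosample 2, from depth or signal over background, is a candidate explanation: 94.5% of the highest-decile peaks of biosample 1 were found in biosample 2, against 1.35% of the lowest decile. Sites open in biosample 1 alone stay open as a further part, as 3.41% of its highest-decile peaks met neither a peak nor a hotspot of biosample 2, but 713 of the 1,005 on chromosomes 1 to 19, X and Y lay in the blocks of dense strong peaks, and outside these the share was 1.00%. Depth is unknown and the labels give no difference in handling, so what would lower detection could not be tested.

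The strongest peaks gathered around Mdm2 on chromosome 10 and Cwc22 on chromosome 2. Calls in repeats are argued against, since 19.6% of the peaks there had over 50% of their bases masked. The lower of the 10th percentiles of score percentile in both regions was 82.9, which is 65.0 points above the highest, 17.8 at Nrg1, among 7 other genes (Lin7a was left out because a block lay near it), but the regions were picked for strong peaks and these genes were not, so extra copies of the regions and clusters of strong regulatory sites cannot be told apart by it and both stay open. AP-1 matched 4.43% of the windows of the Mdm2 block and 4.76% of those of the Cwc22 block against 39.0% of all highest-decile distal windows, and their flanks had median percentiles of 19.5 and 14.1, whereas of other blocks that near Lin7a had flanks at 95.5 and that at Lyz2 a 10th percentile of 2.10. No copy number was measured, and although Mdm2 was once isolated from amplified DNA of a transformed 3T3 line and the Cwc22 segment is known to vary in copy number among mouse strains, the labels give the strain as C57BL/6J for a line usually described as of Swiss origin, so the strain itself was not settled.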

How the results depend on the processing

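The promoter comparison within score deciles and the tests within CpG classes, without the blocks and of the stronger 50% of a list against the whole other list were added after the results were seen. No paired analysis was possible because each biosample had 1 list. Of the main values under all alternatives 35 stayed within their error, on their side of the threshold or, for counts of lists and motifs, near the main count. Such counts include changes from 4 to 6 lists open less often and from 5 to 4 lists open more often. A further 20 values moved and 2 reversed. Requiring 50% of the shorter peak gave 89.1% of biosample 2 and 28.9% of biosample 1 peaks shared, 98.4% and 30.3% of hotspots, and a rho of 0.913. The stronger 50% of each list gave 97.8% and 32.3%, the stronger 50% of a list against the whole other list 97.8% and 57.3%, and lists of equal length 77.2% and 76.5%, where the shortened list itself lowers or raises the value. The promoter share of biosample 1 was 8.77% at 500 bp, 18.7% at 2000 bp and 19.9% in the stronger 50%, and that of biosample 2 was 17.1%, 25.7% and 27.8%, where the window's width sets the values at 500 and 2000 bp. The promoter odds ratio of shared peaks reversed within score deciles, to 0.561 and, with hotspots, 0.706. Lists open more often went from 5 to 3 within CpG classes, lists open less often from 4 to 9 at 500 bp, and motifs below controls from 2 to 1 in the stronger 50% of the windows. For the other values, 203 were counted as the same, which for gene lists and motifs meant keeping or still lacking a call, not an unchanged ratio. The odds ratio of the neuron list, for instance, was 0.309 in the main setting and 1.12 with a promoter window of 2000 bp. Of the rest, 19 became called, 14 lost their call and 1 moved (the share of highest-decile biosample 1 peaks with no counterpart, 1.00% without the blocks). The other 4 reversed: MEF2 (0.575 against flanking windows not matched for GC content) and, for the distal peaks of biosample 1 and of biosample 2 in turn, NRF1 (0.808 and 2.60), MEF2 (0.960 and 1.11) and SRF (0.981 and 1.14), the biosample 1 values being the reversed ones. Except where the construction is named, the cause was not tested. Unknown depth limits every count of sites in biosample 2.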

Other observations

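The promoter motif counts, and the AP-1 and CTCF values outside the blocks, were chosen after the distal results were seen. Of 15,937 promoter windows, those of 18,646 for which a control of equal GC content was found, 10.4% matched NFY, the CCAAT-box factor, against 1.70% of controls (odds ratio 6.73, 5.90 to 7.66), although NFY did not pass at distal sites. ETS motifs were found in 5.29% against 0.238% (23.4, 16.9 to 32.4), SP/KLF in 8.58% against 2.06% (4.47, 3.95 to 5.05), CRE in 2.10% against 0.188% (11.4, 7.83 to 16.6) and NRF1, a regulator of respiratory chain genes, in 1.03% against 0.0376% (27.6, 12.2 to 62.4). AP-1 was found in 7.23% against 1.95% (3.92, 3.45 to 4.45) and CTCF in 2.25% against 0.370% (6.18, 4.69 to 8.15). The consensus sequences of ETS, SP/KLF, CRE and NRF1 each hold a CpG, and the controls were not matched for CpG content. Their ratios therefore cannot be told apart from the CpG content of promoters. The difference between promoter and distal windows was not itself tested.

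Distal peaks of biosample 1 alone also carried AP-1 (18.8% against 2.90% of controls, odds ratio 7.75) and CTCF (2.19% against 0.207%, 10.8). AP-1 matches of shared peaks against peaks of biosample 1 alone had an odds ratio of 1.17 over score deciles. This lay below the 1.2 set beforehand for a difference and above the 1.1 set as the upper bound for none. Outside the blocks it was 1.096 (1.06 to 1.13), just under that bound, with an interval that passes it. Whether AP-1 sites are called in both biosamples more often than other sites of like score was therefore not settled, and any such difference was small. For CTCF the ratio outside the blocks was 4.01 (3.77 to 4.27). The peaks of biosample 2 with no counterpart lay at a median score percentile of 18.6, and 79.3% of them lay in a hotspot of biosample 1 or within 150 bp of one of its peaks.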
